A study of Homo sapiens with 12 samples.

How the data were processed

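RNA was sequenced from 12 libraries of BEAS-2B human bronchial epithelial cells, 3 each of untreated control, TGF-β1 (40 pM, 24 h), dexamethasone (30 nM, a further 4 h) and both, after 24 h without serum. Per the labels, total RNA was purified on columns, 500 ng with an RNA integrity number above 8 went into each library, and polyadenylated RNA was isolated before a non-directional library kit. Per the labels, reads were assigned to genes with featureCounts on genome build hg38; its version, the aligner, the annotation release, the strand setting and the vehicle of the treatments are not given in the sources used here. The growth protocol names A549 cells and all other label fields name BEAS-2B, and no library was reassigned.

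The deposited values are raw read counts per gene, one column per library, which the authors did not normalise. The table held 28395 Entrez gene identifiers and 18 count columns. The labels match 12 columns to libraries; the other 6 have no label and were not used here. The values were whole numbers with totals that differed between libraries. Identifiers were joined to the RefSeq gene table of GRCh38.p14 for symbols, chromosomes and positions. Of these, 27745 matched, which hold 99.943% of counts. The 650 that did not match stayed in the counts under their identifier and were not eligible as named genes. In the 12 libraries 3893 identifiers had no count. Total counts per library ran from 5861591 to 19727235. Replicate 3 of each group had at least 17968961 counts, and replicates 1 and 2 had at most 7008203. Counts of replicate pairs differed by more than sampling noise (chi-square per degree of freedom 6 to 18.21), so tests used the spread between libraries. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

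Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 13469. All 12 libraries were fitted in 1 model with a mean per group, TMM normalisation, robust dispersion and edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors were derived from the log2 fold change and the F statistic. Levels are CPM on TMM-scaled library sizes, and principal components used log2 CPM with a prior count of 2. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

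The comparisons were TGF-β1 against control, dexamethasone against control, both against TGF-β1, both against dexamethasone, both against control and TGF-β1 against dexamethasone. The interaction was the dexamethasone effect with TGF-β1 minus that without it. For the response as a whole, genes were chosen on the mean dexamethasone effect over both backgrounds (adjusted p under 0.05, log2 fold change of at least 1 in size). In a balanced design the error of that mean is uncorrelated with the error of the interaction if the groups have equal spread. Fry tested the interaction of the set, with p adjusted over the induced and the repressed set, an adjustment added after the data were seen. Slopes were taken through 0 by least squares and also with error in both effects. Whether libraries of the same number share a deviation was checked by correlating residuals after removal of the group mean; the rule was a correlation over 0.1 for all 18 pairs of libraries with the same number, which held for 18. The common biological coefficient of variation was 0.1217 without and 0.0577 with the number as a block. The tests described first are without the block, as fixed beforehand.

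The 27 gene lists, the rule for named genes, the comparisons and the alternatives were fixed before the data were examined. The lists were glucocorticoid-induced genes, inflammatory mediators, SMAD feedback and targets, extracellular matrix, mesenchymal, epithelial, actin and cofilin, glucocorticoid receptor machinery, metallothioneins, circadian clock, ERK feedback, immediate-early genes, cell cycle, interferon-stimulated genes, NF-κB feedback, cholesterol synthesis, the ATF4 and unfolded protein responses, hypoxia and glycolysis, integrins, the Notch pathway, transcripts abundant in A549 cells, and markers of fibroblasts, leukocytes, endothelium, airway secretory and ciliated cells, mitochondrial DNA and haemoglobin. Some genes stand in more than 1 list. The 24 lists with at least 5 tested members were tested in 7 comparisons with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Of 168 such tests 71 passed, 8 of which held with an estimated correlation, 69 with the block, and 9 with both.

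Named genes were 18 genes fixed by name, plus up to 10 genes with the largest rise and up to 10 with the largest fall per main comparison, plus up to 3 members per list and direction. The largest rises and falls were taken among genes past the test with a mean log2 CPM of at least 1, no overlap between the libraries of the compared groups (not required for the interaction) and a symbol that is not of a clone, noncoding or pseudogene kind. Part of them is named in the text, and some are not reported here. Where a named gene had 3 reads or fewer over a group, the ratio of scaled reads with its exact binomial 95% interval was given, or a bound from a floor of 3 counts where there were none.

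Alternatives were RLE size factors, scaling by library size alone, no filter, a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, fits to the 6 libraries of a comparison, omission of each library in turn, other ways to choose the dexamethasone genes, and camera with an estimated correlation or fry. Camera with an estimated correlation together with the block, and all libraries thinned at random to the smallest total, were added after the data were seen. On counts simulated from the means and dispersions of these libraries, 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, and of those past the filter TGF-β1 against control recovered 43.9%, 77.8% and 95.4% and the interaction 18.5%, 66.7% and 90.9%; false calls made up 2.78% and 5.71%. A simulated slope of 0.7 was returned as 0.715 and one of 1 as 0.986. The simulated libraries shared no deviation by replicate number, and the genes of the slopes were all raised and had no TGF-β1 effect. Recovery in the measured libraries may therefore differ.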

Results

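Gene expression was measured by RNA sequencing in 12 libraries of BEAS-2B cells, a line of human bronchial epithelial cells immortalised with viral genes. The libraries formed 4 groups of 3: untreated control, TGF-β1 (40 pM, 24 h), dexamethasone (30 nM, 4 h) and both. TGF-β1 is a growth factor that drives matrix production, and dexamethasone is a synthetic glucocorticoid that activates the glucocorticoid receptor. The labels put the TGF-β1 treatment before dexamethasone, after 24 h without serum, and call the 3 libraries of a group biological triplicates. The growth protocol of the labels names A549 cells, whereas the source, the cell type and the treatment protocol name BEAS-2B. Levels below are CPM (normalised counts scaled to a common library total), mean ± SD over n = 3 libraries, and effects are log2 fold changes with their standard error (SE) from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 13469 genes tested.

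Total counts per library lay between 5861591 and 7008203 in replicates 1 and 2 and between 17968961 and 19727235 in replicate 3 of every group. The fibronectin gene FN1 alone took 1.43% to 2.63% of all counts in the 6 libraries with TGF-β1. Mitochondrial transcripts made up 3.44% to 3.85% of counts in the 6 libraries without TGF-β1 and 2.36% to 3.06% in the 6 with it. These are shares of raw counts. After normalisation, 0 of the 13 listed mitochondrial protein-coding transcripts were past the edgeR test in TGF-β1 against control, and 4 fell with the replicate block. The camera adjusted p of that list was 0.238, and 0.0357 with the block (0.722 and 0.598 with an estimated correlation). Component 1 of the principal components (52.5% of variance) separated the libraries by TGF-β1 and component 2 (22.5%) by dexamethasone. Component 3 (8.4%) separated replicate 2 of each group from replicates 1 and 3. After the group mean was removed, libraries with the same number in different groups correlated across genes at 0.25 to 0.541, and libraries with different numbers at -0.422 to 0.042. Removal of a group mean makes the deviations of its libraries cancel, so the values for different numbers are not separate evidence. Genes are not independent replicates, so these correlations have no p. The replicate number was therefore also fitted as a block, and the blocked value stands beside a result where it changed a call or moved a count by over 1.5 times. Figures show values without the block.

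**Figure D1:**
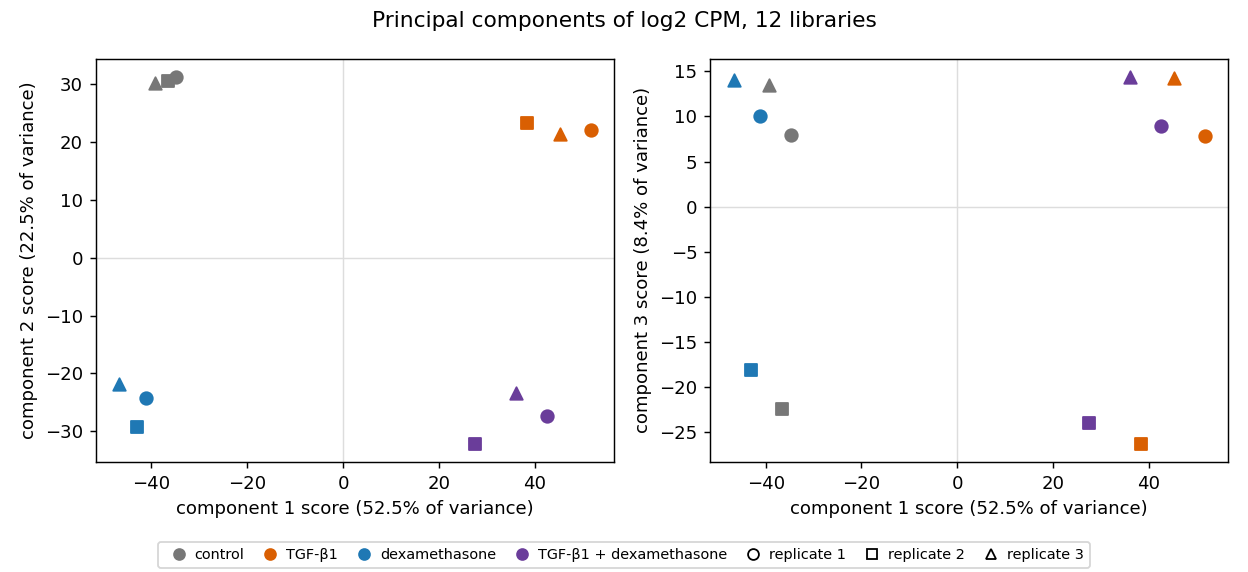
Scores of the 12 libraries on components 1 and 2 (left) and 1 and 3 (right) of log2 CPM; colours show the 4 groups and shapes the replicate numbers. TGF-β1 separates along component 1 (52.5% of variance), dexamethasone along component 2 (22.5%), and replicate 2 along component 3 (8.4%).

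The effect of TGF-β1 alone was taken from TGF-β1 against control. TGF-β1 raised most genes of the extracellular matrix and mesenchymal lists and lowered part of the cell cycle, interferon-stimulated and epithelial lists. The calls of these 5 lists were lost with an estimated correlation (adjusted p from 0.0611 to 0.0685), as given with each list below. TGFBI, which encodes a matrix protein named after its induction by TGF-β, rose from 237.1 ± 41.1 to 10980 ± 1450 CPM (log2 fold change 5.54, SE 0.20, adjusted p = 5.18e-10). COL1A1, the alpha-1 chain of type I collagen, rose from 572.7 ± 109 to 10620 ± 1290 CPM (4.21, SE 0.20, adjusted p = 7.41e-09). OAS1, an interferon-induced sensor of double-stranded RNA, fell from 27.77 ± 1.61 to 1.59 ± 0.236 CPM (-4.13, SE 0.16, adjusted p = 1.23e-09). In all, 2186 genes were higher and 2230 lower, of which 698 and 748 changed at least 2-fold. With the replicate block these counts were 3308 and 3433. Scaling by library size alone put the median of all genes at -0.217 and gave 1251 higher and 4332 lower, so that 22.4% of calls were higher in place of 49.5%; the directions below are relative to the median gene.

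By genome build GRCh38.p14, TGFBI (Entrez gene 7045) lies on chromosome 5 from 136028988 to 136063818, COL1A1 (Entrez gene 1277) on chromosome 17 from 50184101 to 50201631, and OAS1 (Entrez gene 4938) on chromosome 12 from 112906962 to 112933219. These 3 genes are annotated as protein-coding, and counts were summed per gene.

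Of 40 tested extracellular matrix genes, 35 rose and 1 fell (35 and 1 adjusted over the list alone; camera adjusted p = 1.23e-19). That call was lost with an estimated correlation (adjusted p = 0.0685 with an estimated correlation). Among those that rose were COL6A3, a chain of type VI collagen (log2 fold change 5.64, SE 0.35), ELN, which encodes elastin (5.04, SE 1.06), and COL1A2, the partner chain of COL1A1 (5.02, SE 0.18). The member that fell was COL8A1, a chain of type VIII collagen (-2.03, SE 0.11). Of 25 SMAD feedback genes and targets, 19 rose and 2 fell (21 and 2 adjusted over the list alone; camera adjusted p = 1.32e-12, adjusted p = 0.0611 with an estimated correlation). SMAD7, the inhibitory SMAD, rose from 13.61 ± 2.85 to 110.7 ± 20 CPM, while SMAD3, a signal transducer of the same pathway, fell from 192.2 ± 21.8 to 92.98 ± 18.7 CPM. ID2, a dominant-negative helix-loop-helix factor, also fell (-2.26, SE 0.33). LEFTY2, a secreted antagonist of the TGF-β family, had 73 reads against 2 in control, a ratio of 41.1 with a counting interval of 11 to 345. CCN2, a matricellular growth factor, was 219.8 ± 82.1 CPM against 129.8 ± 37.5 (adjusted p = 0.0861; 0.0361 with the block).

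Of 24 mesenchymal genes, 16 rose and 2 fell (17 and 3 adjusted over the list alone; camera adjusted p = 2.1e-07, adjusted p = 0.0611 with an estimated correlation). SNAI1, a transcriptional repressor of epithelial genes, rose from 3.284 ± 0.892 to 98.57 ± 12 CPM. SPOCK1, a matrix proteoglycan, rose from 14.84 ± 2.22 to 548.5 ± 14.3 CPM, and FAP, a surface protease of activated fibroblasts, rose by 5.55 (SE 0.89). TWIST1, another factor tied to mesenchymal states, fell (-0.86, SE 0.13, adjusted p = 0.000191), as did S100A4 (-1.44, SE 0.50, adjusted p = 0.0433). Of 37 epithelial genes, 4 rose and 15 fell (4 and 15 adjusted over the list alone; 8 and 18 with the block), with camera adjusted p = 0.00652 and adjusted p = 0.0685 with an estimated correlation. CDH1, which encodes E-cadherin, fell from 99.88 ± 17.5 to 63.64 ± 4.41 CPM. KRT15 fell by 3.22 (SE 0.23) and the desmosomal gene PKP2 by 1.97 (SE 0.17), whereas the keratins KRT17 (1.69, SE 0.35), KRT14 (2.20, SE 0.73) and KRT7 (0.76, SE 0.24) rose. KRT5, a basal cell keratin, was 602 ± 270 CPM against 502.5 ± 140 (adjusted p = 0.625; 0.03 with the block).

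Of 45 actin and cofilin genes, 17 rose and 5 fell (17 and 5 adjusted over the list alone; 27 and 10 with the block), with camera adjusted p = 0.00975 and adjusted p = 0.431 with an estimated correlation. TPM1, a tropomyosin, rose from 326.2 ± 22.9 to 2455 ± 242 CPM, and MYLK, the myosin light chain kinase, rose by 1.57 (SE 0.27). CFL1, the non-muscle cofilin that severs actin filaments, rose by 0.51 (SE 0.09, adjusted p = 0.000522), whereas CFL2, the muscle cofilin, fell (-0.89, SE 0.15). With scaling by library size alone CFL1 was higher by 0.30 (adjusted p = 0.00995). PAK4, a kinase upstream of the cofilin kinases, was 72.71 ± 4.59 CPM against 72.26 ± 5.42 (adjusted p = 0.966).

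Of 32 cell cycle genes, 21 fell and 11 were not past the test (27 fell adjusted over the list alone; 1 rose and 30 fell with the block; camera adjusted p = 3.73e-08, adjusted p = 0.0685 with an estimated correlation). BUB1B, a spindle checkpoint kinase, fell by 0.92 (SE 0.14), and RRM2, a subunit of ribonucleotide reductase, fell by 0.66 (SE 0.08). Of 23 interferon-stimulated genes, 1 rose and 15 fell (1 and 15 adjusted over the list alone; camera adjusted p = 9.84e-07, adjusted p = 0.0611 with an estimated correlation). Beside OAS1, the antiviral genes IFIT2 (-2.71, SE 0.26) and IFIT1 (-2.67, SE 0.24) fell, and IFI44L rose (0.79, SE 0.29). Of 25 genes of the ATF4 and unfolded protein responses, 17 rose and 8 were not past the test (17 rose adjusted over the list alone; camera adjusted p = 1.7e-09, adjusted p = 0.0685 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose from 482 ± 42.8 to 1319 ± 83.7 CPM, and ASNS, asparagine synthetase, rose by 1.41 (SE 0.23).

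Of 21 immediate-early genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.284). JUNB, an AP-1 subunit, rose by 2.63 (SE 0.14) and IER5 fell by 1.25 (SE 0.15). Of 18 genes of feedback on ERK signalling, 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.284). SPRY1, a Sprouty inhibitor of receptor signalling, fell by 3.47 (SE 0.38), and IER3 rose by 1.47 (SE 0.23). Of 17 inflammatory mediators, 4 rose and 8 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.519). IL11, a cytokine of the IL-6 family, rose from 5.278 ± 1.39 to 118.6 ± 22.2 CPM, and MMP3, a matrix-degrading protease, rose by 5.09 (SE 0.51). The interleukin gene IL1B (-3.11, SE 0.48) and the neutrophil chemokine gene CXCL1 (-2.80, SE 0.39) fell.

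The largest falls among genes chosen by the rule were in MLXIPL, a glucose-responsive transcription factor (-5.05, SE 0.40), ATP6V1B1, a subunit of the proton pump (-4.93, SE 0.47), and the adhesion receptor genes ADGRF1 (-4.88, SE 0.78) and ADGRF5 (-4.83, SE 0.49). Beside the genes above, ITGA11, a collagen-binding integrin chain, rose from 2.214 ± 1.1 to 238.1 ± 48.4 CPM. R3HDML had 530 reads with TGF-β1 and 0 in control, which makes it at least 199-fold higher against a floor of 3 counts over the group. LRRC32, a membrane protein that holds latent TGF-β, had 173 reads against 1, a ratio of 195 with a counting interval of 34.5 to 7730. ODAPH rose by 6.58 (SE 0.51), and COMP, a cartilage matrix protein, by 5.84 (SE 0.74).

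Genes of the glucocorticoid response were also measured with TGF-β1 alone. NR3C1, which encodes the glucocorticoid receptor, fell from 305.3 ± 37.8 to 220.8 ± 27 CPM (-0.47, SE 0.14, adjusted p = 0.0224). Of 24 genes of the glucocorticoid receptor machinery, 4 rose and 4 fell (4 and 4 adjusted over the list alone; 7 and 7 with the block; camera adjusted p = 0.63, median 0.06 and mean -0.005). The chaperone gene HSP90AB1 rose by 0.57 (SE 0.07) and its relative HSP90AA1 fell by 0.56 (SE 0.08). Of 30 glucocorticoid-induced genes, 5 rose and 12 fell (6 and 14 adjusted over the list alone), with camera adjusted p = 0.0932, and 0.0342 with the block (0.431 and 0.373 with an estimated correlation). SCNN1A, the alpha subunit of the epithelial sodium channel, fell from 59.75 ± 15.6 to 5.17 ± 1.48 CPM, and FKBP5, a co-chaperone of the receptor, fell from 160.9 ± 17.3 to 97.45 ± 6.53 CPM. KLF9 (-0.93, SE 0.31, adjusted p = 0.0432) and ZBTB16 (-1.29, SE 0.40, adjusted p = 0.0247), both transcription factors, fell. SGK1, a kinase that acts on ion channels, rose from 19.83 ± 4.19 to 74.36 ± 14.1 CPM. TSC22D3 (GILZ) had a log2 fold change of 0.50 (adjusted p = 0.0585), the clock gene PER1 0.01 (adjusted p = 0.945) and CRISPLD2 0.86 (adjusted p = 0.247). DUSP1, a phosphatase of MAP kinases, had -0.55 (adjusted p = 0.0788; 0.00126 with the block), and CDKN1C, the cell cycle inhibitor p57, had -1.55 (adjusted p = 0.139; 0.0319 with the block).

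**Figure D2:**
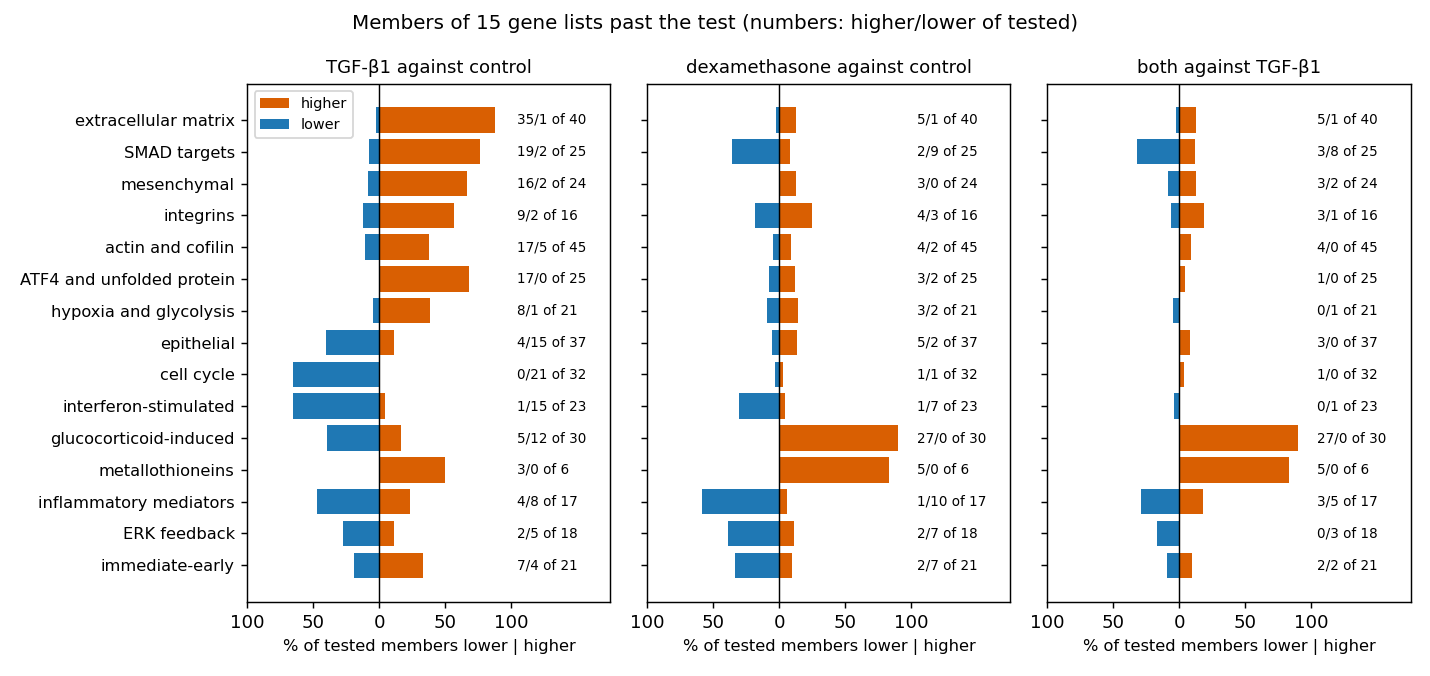
Percent of the tested members of 15 gene lists that were higher (right) or lower (left) in 3 comparisons, with counts of higher and lower members of those tested. Extracellular matrix genes had 35 of 40 higher with TGF-β1, and glucocorticoid-induced genes had 27 of 30 higher with dexamethasone both without and with TGF-β1.

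The glucocorticoid response of cells not given TGF-β1 was taken from dexamethasone against control. Dexamethasone raised nearly the whole list of glucocorticoid-induced genes and metallothionein genes, and lowered part of the inflammatory mediators, interferon-stimulated and ERK feedback genes. The calls of the last 3 lists were lost with an estimated correlation (adjusted p = 0.0701, 0.0748 and 0.265), and that of the metallothioneins with that and the block together (0.173). FKBP5 rose from 160.9 ± 17.3 to 2410 ± 147 CPM (log2 fold change 3.90, SE 0.12, adjusted p = 2.77e-10). KDR, a receptor of vascular endothelial growth factor, rose from 0.2713 ± 0.318 to 227.4 ± 94.4 CPM (9.83, SE 0.53, adjusted p = 5.06e-07). IL6, an inflammatory cytokine, fell from 4.38 ± 1.64 to 0.3764 ± 0.119 CPM (-3.63, SE 0.49, adjusted p = 0.000147). PLK2, a polo-like kinase, fell from 278 ± 27.9 to 38.38 ± 4.82 CPM (-2.87, SE 0.13, adjusted p = 7.48e-09). In all, 746 genes were higher and 660 lower, 352 and 243 of them at least 2-fold; with the replicate block the counts were 1461 and 1535. Of the calls 53.1% were higher, and 43.2% with scaling by library size alone.

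FKBP5 (Entrez gene 2289) lies on chromosome 6 from 35573590 to 35728583, KDR (Entrez gene 3791) on chromosome 4 from 55078481 to 55125595, and IL6 (Entrez gene 3569) on chromosome 7 from 22727200 to 22731998. NR3C1 (Entrez gene 2908) lies on chromosome 5 from 143277931 to 143435512.

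Of 30 glucocorticoid-induced genes, 27 rose and 3 were not past the test (28 rose adjusted over the list alone; camera adjusted p = 2.67e-40, adjusted p = 0.000387 with an estimated correlation). ZBTB16 rose from 2.709 ± 1.49 to 99.77 ± 7.01 CPM. PDK4, a kinase that restrains pyruvate oxidation, rose by 4.89 (SE 0.45), and TFCP2L1, a transcription factor, by 4.46 (SE 0.33). TSC22D3 rose by 3.35 (SE 0.19), DUSP1 by 3.34 (SE 0.21), PER1 by 2.85 (SE 0.11), SCNN1A by 1.27 (SE 0.20), KLF9 by 1.26 (SE 0.30) and CDKN1C by 4.25 (SE 0.62). CRISPLD2 had a log2 fold change of 1.66 (SE 0.50, adjusted p = 0.06; 0.00098 with the block). Of 6 metallothionein genes, which encode metal-binding proteins, 5 rose and 1 was not past the test (6 rose adjusted over the list alone; camera adjusted p = 1.43e-06, adjusted p = 0.016 with an estimated correlation, 0.173 with that and the block). MT1E rose by 3.68 (SE 0.52) and MT1X by 2.24 (SE 0.23). MT1M had 75 reads against 3 in control, a ratio of 24.5 with a counting interval of 8.08 to 122. MT2A stands in both lists.

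Of 17 inflammatory mediators, 1 rose and 10 fell (1 and 10 adjusted over the list alone; 2 and 11 with the block; camera adjusted p = 1.47e-06, adjusted p = 0.0701 with an estimated correlation). Beside IL6, the neutrophil chemokine gene CXCL8 fell by 4.61 (SE 0.66) and the monocyte chemokine gene CCL2 by 3.06 (SE 0.42). CSF2, the growth factor GM-CSF, had 36 reads in control against 1, a ratio of 36.7 with a counting interval of 6.18 to 1490. CSF3, which encodes G-CSF, was the member that rose (2.82, SE 0.62). Of 23 interferon-stimulated genes, 1 rose and 7 fell (1 and 9 adjusted over the list alone; 1 and 12 with the block), with camera adjusted p = 6.02e-06 and adjusted p = 0.0748 with an estimated correlation. IFIT2 fell by 3.15 (SE 0.26) and IFIT3 by 2.46 (SE 0.17). Of 18 ERK feedback genes, 2 rose and 7 fell (2 and 9 adjusted over the list alone; camera adjusted p = 1.39e-05, adjusted p = 0.265 with an estimated correlation). IER3 fell from 63.84 ± 15.5 to 5.763 ± 0.988 CPM and SPRY1 by 2.29 (SE 0.33), whereas FOS (2.59, SE 0.46) and SPRY2 (1.98, SE 0.22) rose. Of 21 immediate-early genes, 2 rose and 7 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.265 with an estimated correlation). IER2 fell by 1.27 (SE 0.11).

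Of 25 SMAD feedback genes and targets, 2 rose and 9 fell (2 and 11 adjusted over the list alone; camera adjusted p = 0.00205, adjusted p = 0.523 with an estimated correlation). IL11 fell by 1.84 (SE 0.31), SMAD3 by 1.46 (SE 0.14) and SMAD7 by 1.01 (SE 0.25). CCN2 had a log2 fold change of 0.39 (adjusted p = 0.596) and COL1A1 of -0.15 (adjusted p = 0.75). NR3C1 fell from 305.3 ± 37.8 to 123.8 ± 25.1 CPM (-1.30, SE 0.14, adjusted p = 2.96e-05). Of 24 genes of the receptor machinery, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.968). The deacetylase gene HDAC2 fell by 0.26 (SE 0.07).

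Of 45 actin and cofilin genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone; 8 and 9 with the block; camera adjusted p = 0.894). VCL, which encodes the focal adhesion protein vinculin, rose from 409.5 ± 23.8 to 1117 ± 50.7 CPM, and the cofilin phosphatase genes SSH2 (1.07, SE 0.11) and SSH1 (-0.79, SE 0.12) moved apart. CFL1 had a log2 fold change of 0.08 (adjusted p = 0.759) and PAK4 of -0.21 (adjusted p = 0.175; 0.0117 with the block). Of 37 epithelial genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone; 12 and 4 with the block; camera adjusted p = 0.507). MUC1, a membrane mucin, rose by 1.09 (SE 0.30) and CGN, a tight junction protein, fell by 0.49 (SE 0.12). CDH1 had 0.32 (adjusted p = 0.0797; 0.0121 with the block) and KRT5 0.76 (adjusted p = 0.282; 2.15e-06 with the block). Of 40 extracellular matrix genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone; 11 and 5 with the block; camera adjusted p = 0.707). FSTL3, a follistatin-like antagonist of activin, rose by 1.19 (SE 0.12). Of the 13 listed protein-coding transcripts of mitochondrial DNA, ND4L rose (0.33, SE 0.10) and 12 were not past the test (0 past it adjusted over the list alone; 12 rose with the block). The camera adjusted p of that list was 0.00137, and adjusted p = 0.677 with an estimated correlation.

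The rule for named genes also picked STAC2 (5.82, SE 0.35), BEST2, a chloride channel (5.49, SE 0.60), FRZB, a secreted Wnt inhibitor (5.07, SE 0.43), and LBH, a transcriptional cofactor (4.57, SE 0.15), among the largest rises. LCNL1 had 107 reads with dexamethasone against 1, a ratio of 105 with a counting interval of 18.5 to 4190. CYP24A1, which breaks down vitamin D, had 22 reads in control against 1, a ratio of 22.4 with a counting interval of 3.62 to 925. FOXS1, a forkhead factor (-3.39, SE 0.32), PTHLH, the parathyroid hormone-related protein (-3.17, SE 0.54), and TNFRSF11B, the decoy receptor osteoprotegerin (-2.93, SE 0.48), were among the largest falls.

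The glucocorticoid response of cells given TGF-β1 was taken from both treatments against TGF-β1 alone. With TGF-β1 present, dexamethasone again raised 27 of 30 glucocorticoid-induced and 5 of 6 metallothionein genes and lowered IL6 and IL11. The camera call of the metallothioneins was lost with an estimated correlation and the block together (adjusted p = 0.116). FKBP5 rose from 97.45 ± 6.53 to 1472 ± 216 CPM (log2 fold change 3.91, SE 0.12, adjusted p = 4.9e-10), and ZBTB16 from 1.026 ± 0.65 to 81.34 ± 3.91 CPM (6.0, SE 0.29, adjusted p = 6.6e-08). IL11 fell from 118.6 ± 22.2 to 18.37 ± 4.66 CPM (-2.71, SE 0.19, adjusted p = 5.45e-07). SNAI1 fell from 98.57 ± 12 to 43.95 ± 7.64 CPM (-1.16, SE 0.14, adjusted p = 7.07e-05). In all, 686 genes were higher and 406 lower, 316 and 139 of them at least 2-fold; with the block the counts were 1275 and 1078. Of the calls 62.8% were higher, and 53.8% with scaling by library size alone. Of the genes higher in this comparison, 454 were also among the 746 higher with dexamethasone alone, where 38 would be shared by independent lists; of those lower, 268 were shared, where 19.9 would be. These 2 comparisons had no library in common.

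Of 30 glucocorticoid-induced genes, 27 rose and 3 were not past the test (29 rose adjusted over the list alone; camera adjusted p = 8.98e-46, adjusted p = 0.00021 with an estimated correlation). PDK4 rose by 5.42 (SE 0.70), TFCP2L1 by 5.01 (SE 0.36), DUSP1 by 4.29 (SE 0.22), SCNN1A by 2.93 (SE 0.25), PER1 by 2.89 (SE 0.11), TSC22D3 by 2.40 (SE 0.19), KLF9 by 1.82 (SE 0.31) and CDKN1C by 4.67 (SE 0.69). CRISPLD2 had 1.57 (SE 0.46, adjusted p = 0.0694; 0.000772 with the block). Of 6 metallothionein genes, 5 rose and 1 was not past the test (6 rose adjusted over the list alone; camera adjusted p = 9.94e-09, adjusted p = 0.00617 with an estimated correlation, 0.116 with that and the block). MT1M had 101 reads against 3, a ratio of 35.6 with a counting interval of 11.8 to 176, and MT1E rose by 4.09 (SE 0.56). Of 17 inflammatory mediators, 3 rose and 5 fell (3 and 7 adjusted over the list alone; 3 and 8 with the block), with camera adjusted p = 0.0565, and 0.00978 with the block (0.661 and 0.146 with an estimated correlation). IL6 fell by 3.02 (SE 0.49) and CSF2 by 2.95 (SE 0.58), whereas CXCL5, a neutrophil chemokine (1.5, SE 0.30), and CSF1, the macrophage growth factor (0.83, SE 0.13), rose.

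Of 25 SMAD feedback genes and targets, 3 rose and 8 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.0119, adjusted p = 0.661 with an estimated correlation). SMAD3 fell from 92.98 ± 18.7 to 34.75 ± 4.41 CPM, SMAD7 from 110.7 ± 20 to 65.37 ± 8.76 CPM and CDKN2B, a cell cycle inhibitor, from 333.9 ± 40.8 to 130.3 ± 5.5 CPM. CCN2 rose from 219.8 ± 82.1 to 574.4 ± 135 CPM. COL1A1 was 9377 ± 1310 CPM against 10620 ± 1290 (adjusted p = 0.733). Of 40 extracellular matrix genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; 8 and 3 with the block; camera adjusted p = 0.55, median -0.04 and mean 0.07). LOX, which crosslinks collagen, rose by 0.90 (SE 0.24). Of 24 mesenchymal genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; 5 and 6 with the block; camera adjusted p = 0.634); WNT5A, a secreted Wnt ligand, rose by 1.78 (SE 0.39). Of 37 epithelial genes, 3 rose and 34 were not past the test (4 rose adjusted over the list alone; 9 rose and 2 fell with the block), with camera adjusted p = 0.213, and 0.00978 with the block (0.661 and 0.198 with an estimated correlation). The keratin genes KRT7 (0.92, SE 0.24) and KRT8 (0.70, SE 0.12) rose, while CDH1 had 0.32 (adjusted p = 0.103; 0.0203 with the block) and KRT5 0.68 (adjusted p = 0.394; 6e-06 with the block).

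NR3C1 fell further, from 220.8 ± 27 to 133.7 ± 15.7 CPM (adjusted p = 0.0052). CFL1 (0.09, adjusted p = 0.722) and PAK4 (-0.07, adjusted p = 0.808) were not past the test. The rule for named genes also picked KDR (7.39, SE 0.49), EDN2, an endothelin (5.24, SE 0.88), SGPP2, a phosphatase of sphingosine 1-phosphate (4.92, SE 0.18), and STAC2 (4.44, SE 0.30) among the largest rises. Among the largest falls were CYP24A1 (-3.46, SE 0.22), TNFSF15, a cytokine (-3.40, SE 0.48), the growth factor gene FGF5 (-2.97, SE 0.71) and LIF, a cytokine of the IL-6 family (-2.34, SE 0.32).

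**Figure D3:**
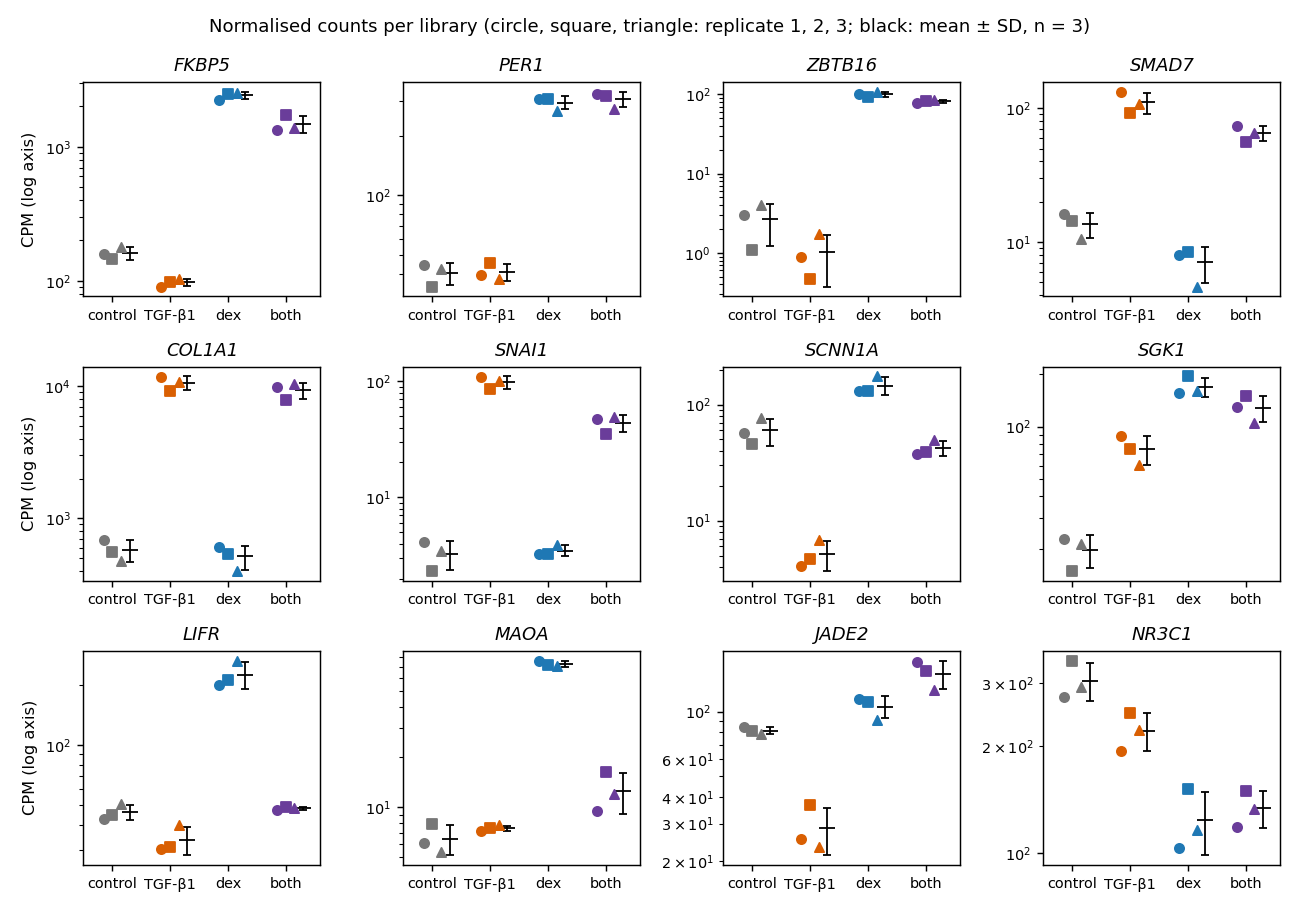
Normalised counts (CPM) of 12 genes in each library on log axes, with mean and SD of n = 3 in black. FKBP5 is highest with dexamethasone (2410 ± 147 CPM), SMAD7 is highest with TGF-β1 (110.7 ± 20 CPM), and LIFR and MAOA stand out with dexamethasone alone (225.9 ± 34.9 and 72.88 ± 2.92 CPM).

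The series title names glucocorticoid insensitivity after TGF-β1, and the interaction tested that question gene by gene: whether the dexamethasone effect differed with and without TGF-β1. The interaction was past the test for 119 of 13469 genes, 65 positive and 54 negative (961 at an unadjusted p under 0.05). With the replicate block the counts were 406 and 238, and 117 of the 119 were among them. Omission of 1 library gave 34 to 67 positive and 22 to 53 negative ones. A count fell by over 1.5 times without control 1, 2 or 3, TGF-β1 1 or 3, dexamethasone 2 or 3, or both 1 or 3, and without control 1 (35 and 22) 55 of the 119 were kept. LIFR, a subunit of the receptor for LIF, rose with dexamethasone from 46.08 ± 3.93 to 225.9 ± 34.9 CPM without TGF-β1 and was 48.26 ± 1.05 against 33.61 ± 5.48 CPM with it (interaction -1.79, SE 0.18, adjusted p = 0.000372). MAOA, which degrades monoamines, went from 6.447 ± 1.32 to 72.88 ± 2.92 CPM without TGF-β1 and from 7.448 ± 0.279 to 12.54 ± 3.42 CPM with it (interaction -2.82, SE 0.25, adjusted p = 0.000303). JADE2, a chromatin-associated protein, went from 81.39 ± 2.92 to 105.5 ± 12.1 CPM without TGF-β1 and from 28.5 ± 7.12 to 150.2 ± 22.6 CPM with it (interaction 2.04, SE 0.22, adjusted p = 0.000905). LIFR (Entrez gene 3977) lies on chromosome 5 from 38474668 to 38608403, and MAOA (Entrez gene 4128) on chromosome X from 43655006 to 43746817.

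By the fitted dexamethasone effects, 36 of the 119 were raised in both backgrounds, but less with TGF-β1, and 22 were raised in both and more with it. A further 12 were lowered in both and less with TGF-β1, and 3 lowered more. In 46 the fitted effects had opposite signs, in 9 of them with both effects past the test. With the block these numbers were 132, 106, 130, 19, 257 and 37 of 644. Among the glucocorticoid-induced genes, 2 of 30 had a positive and 3 a negative interaction (4 and 5 adjusted over the list alone; 4 and 3 with the block; camera adjusted p = 0.924). By fold, SCNN1A was raised more with TGF-β1 (interaction 1.66, SE 0.32, adjusted p = 0.0328) and so was GADD45A, a stress-response gene (0.97, SE 0.13). SCNN1A rose from a lower level there (TGF-β1 against control -3.44). With both treatments it stayed below its level with dexamethasone alone (both against dexamethasone -1.78). SGK1 (-2.29, SE 0.25), GLUL, glutamine synthetase (-0.96, SE 0.13), and STOM, stomatin (-1.18, SE 0.22, adjusted p = 0.0247; 0.0633 with the block), were raised less. FKBP5 (0.01, SE 0.16), PER1 (0.04, SE 0.15), TSC22D3 (-0.95, SE 0.25, adjusted p = 0.163), ZBTB16 (0.99, SE 0.44), KLF9 (0.56, SE 0.43), CDKN1C (0.42, SE 0.90) and CRISPLD2 (-0.09, SE 0.68) were not past the test of the interaction. Nor were NR3C1 (0.58, adjusted p = 0.362; 2.91e-05 with the block) and DUSP1 (0.96, adjusted p = 0.25; 0.000833 with the block). CCN2 (0.99, SE 0.43), SMAD7 (0.25, SE 0.32), COL1A1 (-0.02, SE 0.24), CDH1 (0.005, SE 0.15), KRT5 (-0.07, SE 0.51), CFL1 (0.02, SE 0.12) and PAK4 (0.14, SE 0.12) were not past it either.

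Among 17 inflammatory mediators, CXCL1 (3.04, SE 0.62) and CXCL5 (2.49, SE 0.38) had a positive interaction and 15 were not past the test (4 positive adjusted over the list alone, and 4 with the block; camera adjusted p = 0.000471, adjusted p = 0.328 with an estimated correlation). Both chemokine genes fell with TGF-β1 alone, CXCL1 to 0.35, 1.392 and 0.897 CPM and CXCL5 to 0.701, 0.928 and 1.122 CPM in replicates 1 to 3. Among 23 interferon-stimulated genes IFIT3 was past the test (1.78, SE 0.26; 3 and 1 adjusted over the list alone and with the block), with camera adjusted p = 0.000471 and adjusted p = 0.328 with an estimated correlation. IFIT3 was already low with TGF-β1 alone, at 6.308, 5.102 and 7.459 CPM in replicates 1 to 3, against 32.748, 30.421 and 23.667 in control. Among 21 immediate-early genes KLF4, a zinc-finger factor, was past it (1.40, SE 0.20; 3 and 1 adjusted over the list alone; 4 and 1 with the block), with camera adjusted p = 0.00772 and adjusted p = 0.328 with an estimated correlation. Of 18 ERK feedback genes 0 were past the edgeR test, 5 positive and 2 negative at an unadjusted p under 0.05 (4 and 2 adjusted over the list alone; 6 and 2 with the block; 1 and 0 by DESeq2; 0 by limma-voom), with camera adjusted p = 0.000273 and adjusted p = 0.466 with an estimated correlation. In the actin list VCL had a negative interaction (-0.67, SE 0.13; 3 positive and 3 negative with the block), and in the mesenchymal list SNAI1 did (-1.27, SE 0.27; 0 and 2 adjusted over the list alone, 2 and 2 with the block). In the matrix list COL8A1 had a positive one (1.23, SE 0.15; 1 and 1 adjusted over the list alone and with the block).

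**Figure D4:**
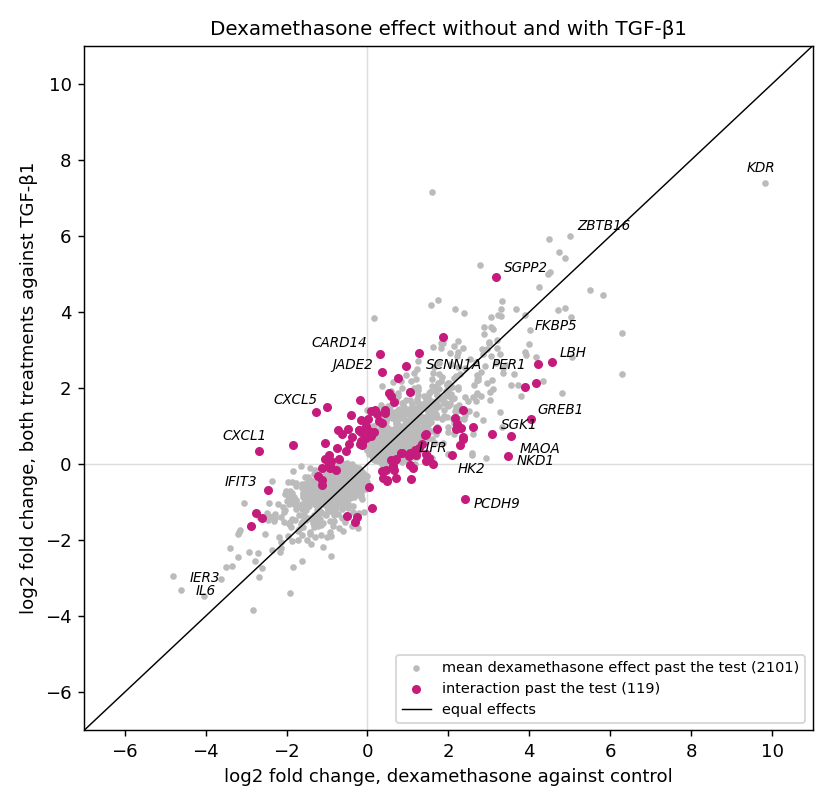
Log2 fold change of dexamethasone with TGF-β1 (vertical axis) against that without TGF-β1 (horizontal axis) for 2101 genes with a mean dexamethasone effect past the test (grey) and 119 genes with an interaction past the test (magenta). FKBP5 and PER1 lie near the line of equal effects, LIFR and MAOA below it, and SCNN1A and JADE2 above it.

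For a view over whole responses, genes were chosen on the mean dexamethasone effect over both backgrounds, at least 2-fold. In this design the error of that mean is uncorrelated with the error of the interaction if the groups have equal spread. Of 360 dexamethasone-induced genes, 198 (55%) had a smaller effect with TGF-β1. Their median effect was 1.70 without and 1.65 with TGF-β1, and the median interaction was -0.09 (per replicate number -0.02, -0.07 and -0.12; fry adjusted p = 0.355). The slope of the effects with TGF-β1 on those without it was 0.85, and 0.944 when both were allowed error. Of 204 dexamethasone-repressed genes, 140 (68.6%) had a smaller fall with TGF-β1. Their median effect was -1.53 without and -1.22 with TGF-β1, and the median interaction was 0.37 (per replicate number 0.31, 0.30 and 0.36; fry adjusted p = 0.00764; 0.0602 without replicate 3 of both, where the median was 0.193). The slope was 0.744, and 0.801 with error in both. IL6 and IER3 were among the repressed genes of both backgrounds. Fry tests whether the genes of a set move one way on balance and does not compare them with other genes. The interaction of the repressed genes was not compared by a test with that of the induced genes.

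The TGF-β1 response with dexamethasone present, both treatments against dexamethasone, had 2145 genes higher and 2207 lower (3229 and 3498 with the block; 1325 and 4472 with scaling by library size alone). Of the 2145 and 2207, 1653 were also higher and 1608 also lower with TGF-β1 alone, where 348.1 and 365.4 would be shared by independent lists. COL1A1 rose from 514.4 ± 106 to 9377 ± 1310 CPM. CDH1 fell from 124.8 ± 1.7 to 79.52 ± 1.44 CPM, SCNN1A from 145.6 ± 25.4 to 42.08 ± 6.17 CPM and FKBP5 from 2410 ± 147 to 1472 ± 216 CPM (adjusted p = 0.000226). SMAD7 rose by 3.32 (SE 0.24), CCN2 by 1.75 (SE 0.31) and CFL1 by 0.52 (SE 0.09). NR3C1 (0.11, SE 0.14), PER1 (0.06, SE 0.10), TSC22D3 (-0.45, SE 0.17), KRT5 (0.19, SE 0.36) and PAK4 (0.14, SE 0.09) were not past the test. With the block DUSP1 (0.41, adjusted p = 0.115; 0.000664), KLF9 (-0.37, adjusted p = 0.388; 0.0103), ZBTB16 (-0.29, adjusted p = 0.259; 0.0365), CDKN1C (-1.14, adjusted p = 0.133; 0.00333) and CRISPLD2 (0.77, adjusted p = 0.207; 0.0322) passed.

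Against control, both treatments together raised 2491 genes and lowered 2434 (1416 and 5342 with scaling by library size alone). SMAD7 was higher by 2.31 (SE 0.22), FKBP5 by 3.19 (SE 0.12) and CRISPLD2 by 2.43 (SE 0.49). NR3C1 was lower by 1.19 (SE 0.14) and CDH1 by 0.34 (SE 0.11). SCNN1A was 42.08 ± 6.17 CPM against 59.75 ± 15.6 (adjusted p = 0.0654; 7.67e-06 with the block), and KRT5 966.9 ± 354 against 502.5 ± 140 (adjusted p = 0.0653; 1.02e-07 with the block). TGF-β1 against dexamethasone gave 2466 genes higher and 2632 lower (4010 lower with scaling by library size alone).

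Over the 13469 genes, the mean TGF-β1 effect and the mean dexamethasone effect correlated at -0.085 (Spearman -0.046; mean over the 3 replicate numbers -0.084, SD 0.017). Genes are not independent replicates, so no p is given. Of the genes lowered by TGF-β1 on average, 410 were raised by dexamethasone, where 271.4 would be by independent lists, and 388 genes were raised by TGF-β1 and lowered by dexamethasone, where 223.2 would be. A further 313 were raised by both, where 253.8 would be, and 254 lowered by both, where 238.7 would be. The excess lies in every pair of directions, and independent lists do not allow for genes that are easier to call in both tests. SCNN1A and IL11 were among the genes moved in opposite directions.

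Because the labels name both lines, transcripts abundant in A549 cells and markers of other cell types were measured. Of the 20 A549 genes, 10 were above 1 CPM. ALDH1A1, a retinal dehydrogenase abundant in A549 cells, averaged 0.1038 CPM, and the aldo-keto reductase genes AKR1C1 and AKR1B10 0.3927 and 2.513 CPM. Of the 10 tested, 4 fell with TGF-β1 and 6 were not past the test (5 fell adjusted over the list alone; 2 rose and 6 fell with the block), with camera adjusted p = 0.0721, and 0.0342 with the block (0.542 and 0.136 with an estimated correlation). Of 6 tested fibroblast markers, 5 rose with TGF-β1 and 1 was not past the test (5 rose adjusted over the list alone; camera adjusted p = 8.97e-07, adjusted p = 0.0611 with an estimated correlation), among them COL1A1 and COL6A3, which the matrix list also holds. Of 5 leukocyte markers, LAPTM5 (3.91, SE 0.65) and CSF1R (3.04, SE 0.31) rose and CD14 fell (-1.71, SE 0.32) with TGF-β1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.265). The pan-leukocyte gene PTPRC averaged 0.06051 CPM. The endothelial, the airway secretory and ciliated, and the haemoglobin lists had 4, 2 and 0 tested members and were not tested. The endothelial list summed to 5.459 ± 0.973 CPM in control and 231.3 ± 95.8 with dexamethasone, of which KDR made up 227 CPM. The secretory and ciliated list summed to 16.85 ± 7.04 CPM in control and 7.888 ± 0.666 with TGF-β1, and the haemoglobin list to 0 ± 0 CPM in control, at most 0.1129 ± 0.1 in the dexamethasone group.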

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

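The tests of scaling, of sequencing depth, of the starting level in held-out replicates, of GC content and length together, and of fibroblasts and endothelial cells were chosen only after the result was seen, as were all counts of other splits. The dexamethasone effect differed with and without TGF-β1, by the test of the difference itself, in 65 genes in the positive and 54 in the negative direction. Of 100 drawn regroupings of the TGF-β1 labels within the dexamethasone strata, the true one included, 4 gave at least its 119 genes. The highest other regrouping gave 6328 and the next 518 and 335, several times the true count. The first exchanges the TGF-β1 labels of 1 stratum in full and leaves the other as it is, and the next 2 exchange all labels of 1 stratum and 1 library per group of the other, which turns much of the mean TGF-β1 effect into the interaction, a structure of the samples. The other regroupings put that effect into the spread between libraries (median common biological coefficient of variation 0.2755, against 0.1217 for the true grouping). The regroupings are therefore no null for the interaction, and whether chance can be excluded stays open.

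Each gene below was singled out by that test of the difference (log2). In the inflammatory mediators list it was 3.04 for CXCL1 and 2.49 for CXCL5, 2 neutrophil chemokines. The camera call of that list was lost with an estimated correlation (adjusted p = 0.328). Outside that list it was 1.88 for PTGES, which makes prostaglandin E2, and 2.58 for CARD14, a scaffold of NF-κB signalling. For the interferon-stimulated IFIT3 it was 1.78. In replicates 1 to 3 IFIT3 stood at 32.748, 30.421 and 23.667 CPM in control and 6.308, 5.102 and 7.459 with TGF-β1. It stood at 5.618, 5.652 and 4.691 CPM with dexamethasone and 4.051, 4.003 and 4.076 with both, so TGF-β1 alone had already lowered it. With TGF-β1 alone CXCL1 stood low, at 0.35, 1.392 and 0.897 CPM in replicates 1 to 3, against 8.49, 6.208 and 4.782 in control. In the same TGF-β1 replicates CXCL5 stood at 0.701, 0.928 and 1.122 CPM and PTGES at 2.103, 1.082 and 1.626. CARD14 stood at 2.794, 2.792, 3.416 and 20.92 CPM in control, TGF-β1, dexamethasone and both. It was 1.66 for the sodium channel gene SCNN1A, 2.64 for the glycosyltransferase gene MGAT4A, 2.35 for the endothelin receptor gene EDNRA, 2.04 for JADE2, 1.74 for the sphingosine phosphatase gene SGPP2 and 1.68 for the repressor gene FOXP4. Negative differences were -3.33 for the protocadherin gene PCDH9, -3.24 for the Wnt antagonist gene NKD1, -2.86 for GREB1, -2.82 for MAOA and -2.29 for SGK1. GREB1 stood at 3.365, 4.194, 60.53 and 10.2 CPM in the same order, and PCDH9 at 2.5, 87.34, 13.7 and 45.56. Others were -2.05 for the channel gene TMEM63C, -1.89 for the transcription cofactor gene LBH, -1.88 for the prostaglandin F receptor gene PTGFR, -1.87 for hexokinase HK2 and -1.79 for the cytokine receptor gene LIFR.

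For the 6 comparisons between groups, 3 against 3 libraries make 10 splits, too few for a share under 0.05, and in each 1 split, the true one, gave as many genes. In fits to the 6 libraries TGF-β1 against control gave 4026 genes, dexamethasone against control 1431, both against TGF-β1 862, both against dexamethasone 3726, both against control 4559 and TGF-β1 against dexamethasone 4542. By edgeR the highest other split gave 0 in each. Of the 10 splits 4, the true one among them, part all 3 replicate numbers between the groups, and the others of these also gave 0. At an unadjusted p under 0.05 the 54 other splits gave 12 to 1265 genes. DESeq2 called at most 34 in them and limma-voom 0. Every other split mixes libraries of both groups on each side, which puts the treatment effect into the spread between libraries. Low counts in them follow from that, so they are no null for these comparisons, and whether chance can be excluded stays open.

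The first pattern weighed is the smaller fall of dexamethasone-repressed genes with TGF-β1. Low counts are argued against by the 55 repressed genes with a mean log2 CPM of 5 or more, whose median interaction was 0.417 (mean over replicate numbers 0.378, SD 0.053), and scaling, which moves all genes alike, by the median of the repressed genes, which exceeded that of all tested genes by at least 0.345 under TMM, RLE and library size alone (SD 0.031). A lower starting level set by TGF-β1 stays open and cannot be told apart from weaker repression. The 120 repressed genes with a mean TGF-β1 effect of 0 or more had a median of 0.226 (0.191, 0.142 and 0.049 per replicate number, mean 0.127, SD 0.072), over 0.1 by more than the SD, which met the bound set beforehand to exclude it, but that bound was wrong, since the mean effect contains part of the interaction and 10 of these genes stood lower with TGF-β1 than in control. Repressed genes not lower with TGF-β1 than in control in 2 replicate numbers had a median in the third of 0.123, 0.132 and -0.008 (mean 0.082, SD 0.078). The 84 repressed genes with a mean TGF-β1 effect under 0 had a larger median, 0.503 (mean over replicate numbers 0.514, SD 0.088).

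The second pattern is the shared deviation of libraries with the same replicate number. Depth is argued against by the median correlation of same-number libraries, 0.333 with all libraries thinned to the smallest total (lowest 0.238), and by the difference of replicates 1 and 2, of like depth, which correlated between groups at 0.313 to 0.441. GC content correlated with the deviation of replicate 2 at 0.062 at most in size. Transcript length reached 0.117 in the dexamethasone group, past its bound of 0.1, yet with the trends of GC content and length removed together the median correlation of same-number libraries was 0.378, against 0.425 before, and the lowest 0.23 (12075 genes, 89.7%). The labels name no batch, no biological explanation was tested, and what the numbers share stays open.

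The third pattern is the rise of fibroblast markers with TGF-β1 and of the endothelial KDR with dexamethasone. Fibroblasts bring COL3A1, DCN and LUM, which summed to at most 0.0134% of COL1A1 in the TGF-β1 libraries (0.6466, 0.1029 and 0.1612 CPM). Of the other fibroblast markers listed, COL1A2, COL6A3, PDGFRB, THY1 and FBLN1 stood at 213.2, 55.29, 189.1, 414.1 and 354.8 CPM with TGF-β1. In control THY1 and FBLN1 already stood at 290 and 230.3 CPM. PDGFRA, DPT and TCF21 stood at 0.9635, 0.0701 and 0.05598 CPM with TGF-β1. Endothelial cells bring PECAM1, VWF and CDH5, which summed to at most 1.27% of KDR in the dexamethasone libraries (1.112, 0.5587 and 0.704 CPM). Both sources are argued against, and transcription of these genes in the treated epithelial cells is a hypothesis found and tested on the same data.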

How the results depend on the processing

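Camera with an estimated correlation in the fit with the block, the adjustment of fry over 2 sets, and libraries thinned to the smallest total were chosen only after the result was seen. Of 168 list tests 71 were calls, and the first kept 9 of these and lost 62, the estimated correlation alone kept 8 and lost 63, and the block kept 69 and lost 2. Direction and side of the threshold, called or not, stayed in 106, 105 and 153 tests, and the block added 13 calls. With fry they stayed in 140, with 9 calls lost and 19 added.

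Among tests of named genes, those that kept direction and side of the threshold, lost the call, gained it and reversed numbered 438, 5, 0 and 0 with RLE, 431, 2, 10 and 0 with DESeq2, and 424, 13, 4 and 2 with limma-voom. They numbered 412, 20, 5 and 6 with library size alone, 408, 34, 0 and 1 with no filter, 412, 3, 0 and 1 with the stricter filter, and 414, 4, 24 and 1 with the block. Of the interaction calls 116, 119, 108, 111, 112, 116 and 117 were kept in the same order. The block changed no other call of those printed here. All 6 comparisons between groups kept their counts within 1.5 times with RLE, DESeq2, limma-voom, both filters and fits to 6 libraries.

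With library size alone, TGF-β1 against control gave 1251 genes higher and 4332 lower, both against dexamethasone 1325 and 4472, both against control 1416 and 5342, and TGF-β1 against dexamethasone 4010 lower. The median of all genes moved to -0.217 for TGF-β1 against control, which this scaling by its construction leaves in, and 3481 of 4416 calls were kept (78.8%). The sign became negative for PER1 (-0.192) and PAK4 (-0.202) with TGF-β1, and for NR3C1 (-0.088), PER1 (-0.148), KRT5 (-0.007) and PAK4 (-0.061) for both against dexamethasone, none past the test.

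With the replicate block, TGF-β1 against control gave 3308 and 3433, dexamethasone against control 1461 and 1535, both against TGF-β1 1275 and 1078, both against dexamethasone 3229 and 3498, and the interaction 406 and 238. The spread it removes is the one the numbers share. PER1 with TGF-β1 was -0.008 there and -0.005 with limma-voom, the CRISPLD2 interaction 0.006 with limma-voom, the CDH1 interaction -0.001 with no filter, and PAK4 with TGF-β1 -0.003 with the stricter filter. With all libraries thinned to the smallest total PER1 and PAK4 with TGF-β1 were -0.004 and -0.005. DESeq2 gave 135 positive interactions. The cause was not tested for these.

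Repressed genes had a median interaction of 0.126 with no minimum on the size (983 genes, adjusted p = 0.00298) and 0.565 chosen on dexamethasone against control alone (adjusted p = 4.16e-05). Induced genes chosen on dexamethasone against control alone had a median interaction of -0.398 (adjusted p = 0.00116). Chosen on both against TGF-β1 alone, induced genes had 0.279 (adjusted p = 0.0292) and repressed genes -0.134 (adjusted p = 0.437). Choice on 1 of the 2 effects shares its error with the interaction by construction.

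Omission of each library in turn kept 4795 gene tests, lost 451, added 25 and reversed 45. It gave 34 to 67 positive and 22 to 53 negative interactions. Positive and negative counts were 35 and 22 without control 1, 39 and 24 without TGF-β1 1, 40 and 33 without TGF-β1 3, 36 and 33 without dexamethasone 3, 34 and 30 without both 1, and 37 and 25 without both 3. Negative ones numbered 32, 31 and 29 without control 2, control 3 and dexamethasone 2. Fewer libraries were compared there, and without control 1, 55 of the 119 calls were kept. The correlation of the 2 mean effects was -0.116 to -0.05, with -0.067 and -0.066 without control 2 and 3, -0.116 and -0.107 without TGF-β1 2 and 3, and -0.05 and -0.054 without both 2 and 3. The median interaction was -0.121 to -0.002 for induced and 0.193 to 0.477 for repressed genes, where the lowest, without both 3, had adjusted p = 0.0602.

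Signs changed, with causes not tested, for these ranges. With TGF-β1, PER1 was -0.081 to 0.084, KRT5 -0.164 to 0.503 and PAK4 -0.044 to 0.059; with dexamethasone COL1A1 was -0.301 to 0.004. For both against dexamethasone PER1 was -0.009 to 0.128 and KRT5 -0.148 to 0.427. Interactions were -0.113 to 0.091 for FKBP5, -0.021 to 0.144 for PER1, -0.477 to 0.87 for CDKN1C, -0.618 to 0.439 for CRISPLD2, -0.079 to 0.474 for SMAD7, -0.176 to 0.129 for COL1A1, -0.093 to 0.145 for CDH1, -0.409 to 0.352 for KRT5 and -0.048 to 0.087 for CFL1. Depth was varied by thinning all libraries to the smallest total, 5861591 counts. Counts of all 6 comparisons and the interaction stayed within 1.5 times, with 1985 and 2054 for TGF-β1 against control and 60 and 44 for the interaction, of which 97 of the 119 calls were kept. Of the gene tests 410 kept direction and side, 27 lost the call, 2 gained it and 2 reversed.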

Other observations

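Camera with an estimated correlation in the fit with the block was chosen only after the result was seen, and counts adjusted over a list alone or with the block are given where they differ, with the block by more than 1.5 times. Of 16 integrin genes, which encode receptors for matrix, 9 rose and 2 fell with TGF-β1 and 5 were not past the test (9 and 3 adjusted over the list alone; camera adjusted p = 0.0149, adjusted p = 0.431 with an estimated correlation). ITGA5, the fibronectin receptor subunit, stood at 114.4 ± 10.5 CPM in control, 502.2 ± 82.2 with TGF-β1, 440.5 ± 90.4 with dexamethasone and 1543 ± 135 with both, so either treatment raised it and they combined. ITGAV rose by 1.79 (SE 0.11) and ITGB8, whose protein activates latent TGF-β with αV, fell by 2.03 (SE 0.18). Dexamethasone raised 4 of the 16, among them ITGA10 (2.71, SE 0.19), and lowered 3 (5 and 5 adjusted over the list alone and with the block; camera adjusted p = 0.677), and with TGF-β1 present raised 3 and lowered 1 (4 and 3 with the block; median -0.025, mean 0.174; camera adjusted p = 0.404). Of 21 hypoxia and glycolysis genes, 8 rose and 1 fell with TGF-β1 and 12 were not past the test (11 and 2 adjusted over the list alone; 15 and 2 with the block; camera adjusted p = 0.00666, adjusted p = 0.431 with an estimated correlation). P4HA1 (1.72, SE 0.38), a collagen prolyl hydroxylase gene, and PFKFB4 (1.44, SE 0.18) rose. Dexamethasone raised CA9 (2.67, SE 0.46), HK2 (2.10, SE 0.26) and 1 more and lowered 2, with VEGFA at -1.96 (SE 0.34; 3 and 4 with the block; camera adjusted p = 0.806). With TGF-β1 present it lowered PFKFB3 (-0.62; 1 rose and 5 fell with the block; camera adjusted p = 0.357), and HK2 had a negative interaction (2 negative with the block; camera adjusted p = 0.227, and 0.0207 with the block; 0.975 and 0.95 with an estimated correlation).

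Of 16 circadian clock genes, TGF-β1 raised 2 and lowered 3 (median 0.127, mean -0.145; camera adjusted p = 0.725): BHLHE40 rose by 2.13 (SE 0.26), and HLF (-4.20, SE 0.80) and DBP (-1.54, SE 0.20) fell. Dexamethasone raised 4, with NPAS2 at 2.61 (SE 0.24) and CIART at 1.31 (SE 0.21), and lowered 3, with BHLHE40 at -1.37 (SE 0.27; median -0.064, mean 0.273; camera adjusted p = 0.654). With TGF-β1 present it raised 3 (4 and 2 with the block; camera adjusted p = 0.278), and NPAS2 had a negative interaction (-1.63, SE 0.34, adjusted p = 0.0379; 2 positive and 1 negative with the block). Of 15 NF-κB feedback genes, dexamethasone raised 4 and lowered 5 (4 and 6 adjusted over the list alone; camera adjusted p = 0.677). NFKBIA, the inhibitor of NF-κB, rose by 2.24 (SE 0.32) and by 2.94 (SE 0.34) with TGF-β1 present, BIRC3 by 2.82 (SE 0.24) and 2.42 (SE 0.42), and BCL3 fell by 1.77 (SE 0.23). With TGF-β1 present 3 rose and 4 fell (camera adjusted p = 0.323), and TGF-β1 alone raised 3 and lowered 3 (3 and 5 with the block; camera adjusted p = 0.327). Of 12 Notch pathway genes, TGF-β1 raised 4, among them the target HEYL (3.13, SE 0.53) and LFNG (2.43, SE 0.34), and lowered 2, among them NOTCH1 (-0.98, SE 0.12; 7 and 3 with the block; camera adjusted p = 0.29). Dexamethasone lowered HES1 (-1.52, SE 0.21) and raised 2, with NOTCH2 at 1.02 (SE 0.13; 4 and 4 adjusted over the list alone; 3 and 5 with the block; camera adjusted p = 0.786), and with TGF-β1 present raised 2 and lowered 3 (4 and 4 adjusted over the list alone and with the block; camera adjusted p = 0.55). Of 24 cholesterol synthesis genes, dexamethasone lowered FDFT1 (-0.34, SE 0.09) and MSMO1 (-0.25, SE 0.07) and 22 were not past the test (1 higher and 4 lower adjusted over the list alone; 1 and 10 with the block; camera adjusted p = 0.0103, adjusted p = 0.813 with an estimated correlation). TGF-β1 raised 1 and lowered 2, with MVK at -0.41 (SE 0.09; 4 and 13 with the block; camera adjusted p = 0.284), and dexamethasone on top of TGF-β1 lowered 1 (8 with the block; camera adjusted p = 0.0802, and 0.00595 with the block; 0.757 and 0.675 with an estimated correlation).

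Interactions of the other lists here had no member past the edgeR test. At an unadjusted p under 0.05 they had 3 positive and 1 negative for integrins, 0 and 2 for Notch, 0 and 1 for NF-κB feedback, and 0 for cholesterol synthesis; DESeq2 called 1 integrin gene and limma-voom 0 genes of these lists. Adjusted over the list alone 1 integrin gene was positive. With the block 3 integrin genes, 2 of NF-κB feedback and 1 of cholesterol synthesis were positive, and in the Notch list 1 was positive and 1 negative.

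A first hypothesis was that dexamethasone folds are larger where TGF-β1 lowers the gene. Among 360 dexamethasone-induced genes the Spearman correlation of the mean TGF-β1 effect with the interaction was 0.022, -0.066 and 0.099 in the 3 replicate numbers, none under the -0.2 that the hypothesis needs. For the mean TGF-β1 effect no such relation was seen. That mean contains part of the interaction, which works against a negative value. The hypothesis therefore stays open for the TGF-β1 effect without dexamethasone. A second was that TGF-β1 acts alike on dexamethasone-induced genes with and without dexamethasone. The slope of its effects with dexamethasone on those without was 0.691 (0.708, 0.642 and 0.795 per replicate number, SD 0.076). It lies below 1 by more than that SD, but error in the effects without dexamethasone lowers such a slope, and with error allowed in both it was 0.94. For 1198 other genes changed by TGF-β1 the slopes were 0.912 and 0.955. A slope of 1 and a weaker effect cannot be told apart here, because error in the measured effects lowers the first slope by an unknown amount.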
